A study of Mus musculus with 11 samples.

How the data were processed

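Total RNA from 11 samples of mouse 3T3-L1 cells was measured on one-colour oligonucleotide arrays with 12488 probe sets, 1 array per sample. Per the labels, the cells received vehicle (0.1% DMSO, 3 arrays), 20 µM pioglitazone (2 arrays), 1 µM rosiglitazone (3 arrays) or 20 µM troglitazone (3 arrays) for 24 h. The titles place the arrays in 2 sets: set 1 holds replicates 1 and 2 of all 4 groups (8 arrays), and set 2 holds replicate 4 of vehicle, rosiglitazone and troglitazone (3 arrays). No protocol text came with the series, and the array software, its version and the summary of probe pairs into probe sets are not given in the sources used here.

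The deposited values are signal intensities on a linear scale, from 0.4 to 224475. The authors had already scaled them: the mean after trimming 2% of the values at each end lay between 500.289 and 500.433 on every array. The values were kept as deposited. Values under a floor of 73.7, the 25th percentile of the pooled values, were raised to it, and base 2 logarithms were taken. After 66 control probe sets were set aside, 12422 probe sets remained, of which 11739 lay above the floor on at least 2 arrays and were tested; 683 did not. Of the tested values, 20.99% lay at the floor. On arrays the depth is the signal over background, so the floor limits how large a fall can be seen in a dim transcript. The number of arrays limits the precision.

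The annotation table pairs 10833 of the 12422 probe sets with 1 gene, 396 with several and 1193 with none. Of the former, 10817 matched the GRCm38.p6 gene table by gene identifier, and 0 symbols needed updating. The files name no genome build, so no coordinates are given. The 10261 tested probe sets with 1 gene cover 7962 genes. In lists and among named genes, a gene is represented by its tested probe set with the highest mean log2 signal over the 11 arrays.

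Differences were estimated with limma 3.58.1 in R 4.3.3: a linear model with a term for each group and a term for the set, fitted to all 11 arrays, leaving 6 residual degrees of freedom. Contrasts were tested two-sided with moderated statistics whose prior variance follows the mean signal (an intensity trend). Within each of the 7 contrasts p-values were adjusted by the Benjamini-Hochberg method, and an adjusted p under 0.05 is meant by "rose", "fell" or "passed". Fold changes are from this model, adjusted for the set, so they can differ from the ratio of the mean signals. Errors of log2 values are standard errors, intervals have 95% confidence, and errors of signals are standard deviations. The contrasts are each drug against vehicle, the mean of the 3 drugs against vehicle, and the 3 pairs of drugs. A model with a mean per group and set tested whether the rosiglitazone and troglitazone effects differ between the sets.

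Gene lists were tested with camera from limma at a preset correlation of 0.01, adjusted over the 30 lists within each contrast. Camera with an estimated correlation and fry were run beside it. The lists cover PPARγ targets and lipid droplets, mitochondrial fatty acid oxidation, peroxisomal lipid metabolism, fatty acid and triglyceride synthesis, cholesterol synthesis and uptake, lipolysis, adipokines, adipogenic transcription factors, insulin signalling, glycolysis, the citric acid cycle, oxidative phosphorylation, thermogenic genes, extracellular matrix, preadipocyte genes, inflammatory genes, glucocorticoid-responsive genes, NRF2 targets, xenobiotic metabolism, endoplasmic reticulum stress, heat shock, cell cycle, ribosomal proteins, the proteasome, and markers of macrophages, skeletal muscle, smooth muscle, osteoblasts and chondrocytes, endothelium and epithelium. Members were chosen from textbook knowledge, and no list was chosen on these samples.

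The scale and floor, the model, the lists, the alternatives below except the last pair, and the rule for naming genes were fixed before the data were examined. The rule takes, for each drug against vehicle, the 10 largest rises and the 10 largest falls among genes that passed and lay on one side of the vehicle mean of their set on each treated array; 5 and 5 for each pair of drugs, or the 5 smallest p-values each way where none passed; up to 4 members of each list that passed; and 32 genes of adipocyte biology whatever their test. Of these 32, 25 were tested. After the values were seen, the report was kept mainly to those of the resulting genes whose call no left-out array ended, and it gives the number of the others.

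Alternatives were quantile normalisation, median centring, floors at the 10th (32.2) and 50th (207.4) percentile, an added constant in place of the floor, no filter on dim probe sets, no set term, set 1 alone, replicate numbers as blocks, no intensity trend, a fit of only the groups compared, the other versions of the list test, and leaving out each array in turn. The last pair, chosen after seeing the data, were the 3' to 5' ratio of the beta-actin control probe sets as a covariate and leaving out the 2 arrays that stand apart. Where leaving out 1 array leaves 1 pioglitazone array, that array is assumed to vary like the others. Replicate numbers were checked as pairs after group means, but not set means, were removed. Arrays of set 1 that share a number correlated between 0.00767 and 0.0932 for replicate 1 and between -0.0989 and 0.0949 for replicate 2. The replicate 4 arrays, which make up set 2, correlated between 0.2894 and 0.3624. These values still hold the difference between the sets. The numbers were not treated as pairs.

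The procedure was tested on simulated data with the design of the rosiglitazone comparison. Over 10 runs with 200 changed probe sets each, it recovered 11.2% of changes of 1 and 36.4% of changes of 2 on the log2 scale. False calls made up 3.63%, and a list of 20 genes shifted by 0.5 was called in 9 of the 10 runs. The simulated noise was drawn independently for each probe set. These rates therefore do not show how often probe sets or lists are called falsely where genes vary together, as on real arrays. Covariances between drug effects were compared with 100 simulated data sets that hold no drug effect and share the vehicle arrays. Exact permutation tests were run in R. Figures were drawn in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9.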

Results

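The series title names treatment of 3T3-L1 cells with troglitazone, pioglitazone and rosiglitazone, and the question taken up here is which transcripts each drug changed after 24 h. A further question is where the drugs differed. 3T3-L1 is a mouse fibroblast line that can be made to differentiate into adipocytes; the labels do not state whether these cells had been differentiated. Transcript signal was measured on 11 arrays: 3 of cells with vehicle, 2 with pioglitazone (20 µM), 3 with rosiglitazone (1 µM) and 3 with troglitazone (20 µM), in 2 sets of 8 and 3 arrays, the smaller without pioglitazone. The number of arrays limits the precision. All 3 drugs are thiazolidinediones, ligands of the nuclear receptor PPARγ. Troglitazone carries a chroman ring like that of vitamin E, and rosiglitazone and pioglitazone carry a pyridine ring. Adipocyte transcripts were bright in the vehicle arrays: Fasn had a mean signal of 15770 ± 2267 (SD, n = 3), Cidec of 10770 ± 2234 and Plin2 of 8683 ± 2185. The median signal of all probe sets of an array lay between 162.8 and 243.5. Signals of different probe sets are not comparable as amounts of transcript, so these values do not settle whether the cells had been differentiated.

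Log2 signals of the 11 arrays correlated pairwise between 0.82 and 0.945. Rosiglitazone replicate 2 stood apart, with a median correlation of 0.833 with the other arrays; without it the lowest pair was at 0.861. Pioglitazone replicate 2 had the beta-actin control 3' to 5' ratio of 4.86, against a median of 2.09 in set 1 and 3.79 in set 2. The 95% interval of a log2 fold change reached a median of 1.04 to each side for pioglitazone and 0.90 for the other drugs, so small changes of single genes could not be resolved. The labels do not say whether the cultures were independent. The p-values here measure only the spread between these samples.

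With pioglitazone (20 µM), Acaa1b, a peroxisomal thiolase of fatty acid oxidation, rose 4.89-fold. On the log2 scale this is 2.29 ± 0.16 (SE, n = 2 against 3 vehicle arrays, limma adjusted p = 4.14e-06), from a signal of 2079 ± 874.7 to 7993 ± 1060 (SD). A dimmer probe set of Acaa1b did not pass with pioglitazone (0.64, adjusted p = 0.427), but did with rosiglitazone (1.16, adjusted p = 0.0195) and troglitazone (1.21, adjusted p = 0.0142). Pck1, an enzyme that supplies glycerol phosphate for triglyceride in adipocytes, rose 4.20-fold (2.07 ± 0.26, adjusted p = 0.000901). Chchd10, a protein of the mitochondrial intermembrane space, rose 6.2-fold (2.63 ± 0.22, adjusted p = 1.43e-05), and Anxa2, a calcium-dependent membrane-binding protein, rose 3.83-fold (1.94 ± 0.14, adjusted p = 5.97e-06). Pparg itself was 3.80-fold lower, a fall by 1.93 ± 0.24 (adjusted p = 0.000901), from a signal of 2182 ± 618.1 to 486.8 ± 34.79. Gsn, the actin-severing protein gelsolin, was 3.74-fold lower (-1.90 ± 0.21, adjusted p = 0.000316), and Hp, the plasma protein haptoglobin, was 3.30-fold lower (-1.72 ± 0.24, adjusted p = 0.00153).

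Further rises with pioglitazone were in Pmm1, a phosphomannomutase (7.89-fold, 2.98 ± 0.38, adjusted p = 0.000901), Cbr3, a carbonyl reductase (3.07-fold, 1.62 ± 0.17, adjusted p = 0.000199), and Retsat, a retinol saturase (2.85-fold, 1.51 ± 0.21, adjusted p = 0.00153). Angptl4, a secreted inhibitor of lipoprotein lipase, rose 2.35-fold (1.23 ± 0.16, adjusted p = 0.00116). Anxa8, another annexin, was 3.17-fold lower (-1.66 ± 0.21, adjusted p = 0.000901). Fasn, fatty acid synthase, was 2.16-fold lower (-1.11 ± 0.16, adjusted p = 0.00315), but without pioglitazone replicate 1 its adjusted p was 0.057 (log2 -0.89). Several classical adipocyte genes did not pass: Adipoq (-0.13), Fabp4 (0.31, adjusted p = 0.611), Lpl (-0.22), Cebpa (-0.10), Cd36 (0.11) and Slc2a4 (0.16).

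Of 53 measured oxidative phosphorylation genes, 10 rose with pioglitazone and 0 fell (26 and 0 adjusted over the list alone), with a median log2 fold change of 0.45 (camera adjusted p = 1.13e-22, and 0.0106 with an estimated correlation). With quantile normalisation this median was 0.277. Ndufa5 of complex I rose 2.82-fold (1.4951 ± 0.15), Atp5o of the ATP synthase 2.26-fold (1.18 ± 0.15) and Uqcrh of complex III 1.87-fold (0.90 ± 0.14). Of 21 PPARγ targets and lipid droplet genes, 7 rose and 0 fell (8 and 1 adjusted over the list alone; median 0.38, camera adjusted p = 8.62e-12, and 0.0171 with an estimated correlation). Among them were the lipid droplet genes Cidec (2.69-fold, 1.43 ± 0.15) and Plin2 (2.45-fold, 1.29 ± 0.16). Of 17 genes of mitochondrial fatty acid oxidation, 4 rose and 0 fell (9 and 1 adjusted over the list alone; median 0.81, adjusted p = 1.8e-09, and 0.0255 with an estimated correlation), such as the thiolase Acaa2 (2.07-fold, 1.05 ± 0.14). Peroxisomal lipid metabolism had 3 of 21 genes higher and 0 lower (8 and 1 adjusted over the list alone; median 0.25, adjusted p = 2.67e-06, and 0.0171 with an estimated correlation). Of 31 extracellular matrix genes, 2 fell and 0 rose (9 fell adjusted over the list alone; median -0.54, adjusted p = 0.000541, and 0.0305 with an estimated correlation). Among 16 genes of cholesterol synthesis and uptake 0 passed singly, but 7 rose adjusted over the list alone (median 0.37, adjusted p = 0.000646, and 0.0344 with an estimated correlation).

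The list of 16 fatty acid and triglyceride synthesis genes had 4 that fell and 1 that rose with pioglitazone (5 and 1 adjusted over the list alone; median -0.12, camera adjusted p = 0.00865, but adjusted p = 0.0757 with an estimated correlation). Thrsp, a regulator of lipogenesis, was 2.49-fold lower (-1.32 ± 0.19, adjusted p = 0.00275), and the sterol and lipogenic transcription factor Srebf1 2.13-fold lower (-1.09 ± 0.18, adjusted p = 0.00665). Without vehicle replicate 2 the adjusted p of this list was 0.061, and it ranged from 3.61e-06 to 0.124 over the alternatives. In the citric acid cycle 3 of 26 genes rose (7 adjusted over the list alone; adjusted p = 1.59e-05, but adjusted p = 0.117 with an estimated correlation). In lipolysis 1 of 8 rose (3 adjusted over the list alone; adjusted p = 0.000924, but 0.124 with an estimated correlation). In glycolysis 1 of 14 rose (3 adjusted over the list alone; adjusted p = 0.000541, but 0.0684 with an estimated correlation). Abhd5, the activator of the triglyceride lipase, rose 2.19-fold (1.13 ± 0.16, adjusted p = 0.00249). Camera further called 21 ribosomal protein genes (median 0.15, adjusted p = 0.000771, and 0.184 with an estimated correlation), 27 proteasome genes (0.12, 0.00847, and 0.389 with an estimated correlation) and 12 preadipocyte genes (-0.65, 0.0189, and 0.184 with an estimated correlation). Each of these 3 calls was lost without pioglitazone replicate 2 (adjusted p = 0.0597, 0.923 and 0.0628). Preadipocyte genes also lost it without vehicle replicate 2 (0.061) or pioglitazone replicate 1 (0.0707), and proteasome genes without vehicle replicate 4 (0.0994).

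In all, limma called 106 of 11739 probe sets with pioglitazone, 74 higher and 32 lower (60 and 27 genes), and camera 13 of 30 lists, 6 of them with an estimated correlation. The count was 59, 43 and 49 without vehicle replicate 4, 1 and 2, 49 without pioglitazone replicate 1, 68 without rosiglitazone replicate 4 and 65 without troglitazone replicate 4. Without pioglitazone replicate 2 it was 111, of which 59 were among the 106, and without the 2 arrays that stand apart 113, of which 44 were. It was 25 with no set term, 23 in set 1 alone, 6 with no intensity trend, and 0 in a limma fit of only the vehicle and pioglitazone arrays (1063 at an unadjusted p under 0.05). Of all probe sets called, 69.8% were higher; with quantile normalisation 48.8% and with median centring 83.5% were, and the median of all genes moved from -0.08 to 0.08 with centring. Of the 44 genes taken by the naming rule that passed, 21 kept the call without any one array.

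With rosiglitazone (1 µM), Chchd10 rose 5.63-fold (2.49 ± 0.19, n = 3 against 3, adjusted p = 4.22e-06), Anxa2 3.95-fold (1.98 ± 0.13, adjusted p = 1.16e-06) and Acaa1b 3.87-fold (1.95 ± 0.14, adjusted p = 1.72e-06). Hsd17b12, a ketoacyl reductase of fatty acid elongation, rose 2.71-fold (1.44 ± 0.21, adjusted p = 0.00183), and Cidea, a lipid droplet protein of brown fat, 2.03-fold (1.02 ± 0.16, adjusted p = 0.00369). Angptl4 rose 2.24-fold (1.16 ± 0.14, adjusted p = 0.000511), and Cidec 2.23-fold (1.16 ± 0.13, adjusted p = 0.000234). Pdcd4, an inhibitor of translation initiation, was 4.96-fold lower (-2.31 ± 0.31, adjusted p = 0.000901), and Pnp, a purine nucleoside phosphorylase, 4.18-fold lower (-2.06 ± 0.30, adjusted p = 0.00159).

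Pparg was 2.70-fold lower with rosiglitazone (-1.43 ± 0.21, adjusted p = 0.00204), with a signal of 805.5 ± 215.5. Cp, the copper carrier ceruloplasmin, was 3.98-fold lower (-1.99 ± 0.27, adjusted p = 0.000965), and Sparcl1, a matricellular protein, 3.93-fold (-1.97 ± 0.30, adjusted p = 0.00266). Itih4, an acute phase protein, was 3.84-fold lower (-1.94 ± 0.22, adjusted p = 0.000333), and Hp 2.91-fold lower (-1.54 ± 0.21, adjusted p = 0.000901). Gsn was 3.73-fold lower (-1.90 ± 0.19, adjusted p = 7.66e-05). Pck1 rose 2.40-fold (1.26 ± 0.23, adjusted p = 0.0102), but not without rosiglitazone replicate 1 (adjusted p = 0.0824) or 2 (0.108). Fabp4 (0.59, adjusted p = 0.0803), Adipoq (-0.02), Lpl (-0.39) and Scd1 (-0.53, adjusted p = 0.267) did not pass.

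Of the 53 oxidative phosphorylation genes 11 rose with rosiglitazone and 0 fell (21 and 0 adjusted over the list alone; median 0.40, camera adjusted p = 2.13e-19, and 0.0162 with an estimated correlation). Examples are Ndufa5 (2.01-fold, 1.01 ± 0.13) and Uqcrb of complex III (1.90-fold, 0.93 ± 0.13). PPARγ targets and lipid droplet genes had 8 of 21 higher (9 and 1 lower adjusted over the list alone; median 0.27, adjusted p = 3.23e-08, and 0.0259 with an estimated correlation). Fatty acid oxidation had 4 of 17 higher (10 and 1 lower adjusted over the list alone; median 0.52, adjusted p = 3.81e-10, and 0.0259 with an estimated correlation). Among them was Hadhb of the trifunctional protein (2.08-fold, 1.05 ± 0.12, adjusted p = 0.000426). Of 14 glycolysis genes 4 rose (8 adjusted over the list alone; median 0.56, adjusted p = 1.36e-09, and 0.0213 with an estimated correlation). Peroxisomal lipid metabolism (4 of 21 rose, median 0.34, adjusted p = 0.00298, and 0.048 with an estimated correlation; 6 and 1 lower adjusted over the list alone) was also called. So was cholesterol synthesis and uptake (1 of 16 rose, 5 adjusted over the list alone, median 0.34, adjusted p = 0.000278, and 0.0259 with an estimated correlation).

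Among 16 genes of fatty acid and triglyceride synthesis 3 fell and 1 rose with rosiglitazone (5 and 1 adjusted over the list alone; median -0.32, camera adjusted p = 0.000137, and 0.0259 with an estimated correlation). Thrsp was 2.51-fold lower (-1.33 ± 0.17, adjusted p = 0.000621), Fasn 2.25-fold (-1.17 ± 0.14, adjusted p = 0.000525) and Srebf1 2.13-fold (-1.09 ± 0.15, adjusted p = 0.00125). Of 31 extracellular matrix genes 3 fell (6 adjusted over the list alone; median -0.26, adjusted p = 0.00441, and 0.048 with an estimated correlation), a call lost without rosiglitazone replicate 1 (adjusted p = 0.0576; range 0.00326 to 0.0576 over the alternatives). The citric acid cycle (4 of 26 rose, 9 adjusted over the list alone; adjusted p = 1.41e-06) stood at adjusted p = 0.0819 with an estimated correlation. Lipolysis (1 of 8 rose, 2 adjusted over the list alone; 0.00298) stood at adjusted p = 0.135 with an estimated correlation, and its Abhd5 rose 2.03-fold (1.02 ± 0.14, adjusted p = 0.00121).

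The lists of thermogenic, inflammatory and NRF2 target genes stood at adjusted p = 0.0467 each with rosiglitazone, and at 0.135, 0.177 and 0.122 with an estimated correlation. Of 9 thermogenic genes 1 rose (1 adjusted over the list alone), and of 22 inflammatory genes 2 fell (2 adjusted over the list alone). Of 26 NRF2 targets 2 fell (3 adjusted over the list alone), including Gstm1, a glutathione transferase (1.99-fold lower, -0.99 ± 0.14, adjusted p = 0.00104). A dimmer probe set of Gstm1 pointed the other way with rosiglitazone without passing (0.275, limma adjusted p = 0.883). The thermogenic call was lost without vehicle replicate 4 (adjusted p = 0.14) or 2 (0.054), rosiglitazone replicate 4 (0.0942) or 1 (0.279), or troglitazone replicate 4 (0.055) or 1 (0.0541). The inflammatory call was lost without vehicle replicate 4 (0.231) or 1 (0.0518), pioglitazone replicate 1 (0.0687) or 2 (0.0677), or rosiglitazone replicate 4 (0.102) or 1 (0.271). The NRF2 call was lost without vehicle replicate 4 (0.13) or 2 (0.136), rosiglitazone replicate 4 (0.106), 1 (0.0545) or 2 (0.0901), or troglitazone replicate 4 (0.055).

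Rosiglitazone changed 159 probe sets, 92 higher and 67 lower (78 and 52 genes), and 13 lists, 8 of them with an estimated correlation. Of these 57.9% were higher; with quantile normalisation 69 were higher and 70 lower, and with no set term 17 and 23. The count was 74, 74 and 76 without vehicle replicate 4, 1 and 2, and 90, 82 and 77 without rosiglitazone replicate 4, 1 and 2. It was 40 with no set term, 19 in set 1 alone, 6 with no intensity trend, 99 with no filter, 18 in a fit of only the 2 groups, and 58 without the 2 arrays that stand apart. Of 58 named genes that passed, 25 kept the call without any one array.

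With troglitazone (20 µM), Chchd10 rose 9.01-fold (3.17 ± 0.19, n = 3 against 3, adjusted p = 5.78e-07), Pmm1 6.59-fold (2.72 ± 0.33, adjusted p = 0.000238) and Pdk4, a kinase that shuts down pyruvate dehydrogenase, 3.98-fold (1.99 ± 0.27, adjusted p = 0.000765). Acaa1b rose 3.89-fold (1.96 ± 0.14, adjusted p = 1.62e-06) and Plin2 2.98-fold (1.57 ± 0.14, adjusted p = 2.13e-05). Genes of the stress response rose as well: Ppp1r15a, the phosphatase subunit that reverses eIF2α phosphorylation, 4.16-fold (2.06 ± 0.22, adjusted p = 0.000104), and Ddit3, the transcription factor CHOP, 2.84-fold (1.5046 ± 0.14, adjusted p = 3.05e-05). Ero1a, an oxidase of the endoplasmic reticulum, rose 2.76-fold (1.46 ± 0.14, adjusted p = 3.05e-05), and Atf4, a transcription factor of the same response, 1.65-fold (0.73 ± 0.11, adjusted p = 0.00267). The metallothioneins Mt2 and Mt1, which bind zinc and copper, rose 2.45-fold (1.29 ± 0.13, adjusted p = 6.13e-05) and 1.86-fold (0.89 ± 0.14, adjusted p = 0.00205). Mmp11, a matrix protease, rose 2.86-fold (1.52 ± 0.19, adjusted p = 0.000297).

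Hp was 4.49-fold lower with troglitazone (-2.17 ± 0.21, adjusted p = 3.05e-05), and Cp 4.22-fold (-2.08 ± 0.27, adjusted p = 0.000459). Orm1, the plasma protein orosomucoid, was 3.23-fold lower (-1.69 ± 0.27, adjusted p = 0.00358), and Retn, the adipokine resistin, 3.20-fold lower (-1.68 ± 0.19, adjusted p = 0.000133). Pparg was 3.71-fold lower (-1.89 ± 0.21, adjusted p = 0.000133), Pdcd4 3.93-fold (-1.98 ± 0.31, adjusted p = 0.00255), Gsn 3.49-fold (-1.80 ± 0.19, adjusted p = 6.13e-05) and Anxa8 3.38-fold (-1.76 ± 0.18, adjusted p = 6.13e-05). Angptl4 and Cidea rose 2.18-fold (1.12 ± 0.14, adjusted p = 0.00034) and 2.19-fold (1.13 ± 0.16, adjusted p = 0.00119). Pck1 did not pass (0.11 ± 0.23, adjusted p = 0.975), nor did Adipoq (-0.48, adjusted p = 0.116), Scd1 (-0.76, adjusted p = 0.0657) or Dlk1, a preadipocyte marker (-0.80, adjusted p = 0.0738). Another bright probe set of Scd1, the stearoyl-CoA desaturase, did pass with troglitazone (-0.64, adjusted p = 0.0401) and for the mean of the drugs (-0.53, adjusted p = 0.0297).

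Of 14 glycolysis genes 8 rose with troglitazone (9 adjusted over the list alone; median 0.69, camera adjusted p = 9.61e-15, and 0.0119 with an estimated correlation), such as hexokinase Hk2 (1.99-fold, 0.99 ± 0.16, adjusted p = 0.00355). The glucose transporter Slc2a1 rose 3.98-fold (1.99 ± 0.32, adjusted p = 0.00321), but not without troglitazone replicate 4 (adjusted p = 0.0616; range 0.00209 to 0.181). Of 16 genes of fatty acid and triglyceride synthesis 4 fell and 1 rose (7 and 1 adjusted over the list alone; median -0.42, adjusted p = 8.18e-07, and 0.0189 with an estimated correlation). Thrsp was 3.60-fold lower (-1.85 ± 0.17, adjusted p = 2.35e-05) and Fasn 3.11-fold lower (-1.64 ± 0.14, adjusted p = 2e-05). Of 19 endoplasmic reticulum stress genes 3 rose and 0 fell (7 and 1 adjusted over the list alone; median 0.28, adjusted p = 2.02e-05, and 0.0473 with an estimated correlation). Of 21 PPARγ targets and lipid droplet genes 6 rose (7 and 1 lower adjusted over the list alone; median 0.21, adjusted p = 4.01e-07, and 0.0358 with an estimated correlation). Of 53 oxidative phosphorylation genes 5 rose (8 adjusted over the list alone; median 0.22, or 0.106 with quantile normalisation, adjusted p = 1.51e-08, and 0.0358 with an estimated correlation). Of 31 extracellular matrix genes 5 fell (7 adjusted over the list alone; median -0.31, adjusted p = 0.00021, and 0.0358 with an estimated correlation).

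Fatty acid oxidation (3 of 17 rose, 5 and 1 lower adjusted over the list alone, median 0.25, adjusted p = 3.82e-05) lost its call with an estimated correlation (adjusted p = 0.0674). Its member Hadhb rose 1.92-fold (0.94 ± 0.12, adjusted p = 0.00059). So did peroxisomal lipid metabolism (2 of 21 rose and 1 fell, 6 and 2 adjusted over the list alone, adjusted p = 0.00734, and 0.0674 with an estimated correlation). That call was also lost without vehicle replicate 4 (adjusted p = 0.0539) or troglitazone replicate 4 (0.0748). The citric acid cycle (2 of 26 rose, 6 adjusted over the list alone) stood at 1.49e-06, and at adjusted p = 0.0826 with an estimated correlation. Inflammatory genes (2 of 22 fell, 2 adjusted over the list alone) stood at 0.033 with camera, at adjusted p = 0.145 with an estimated correlation, at 0.186 without vehicle replicate 4 and at 0.142 without troglitazone replicate 4. Glucocorticoid-responsive genes (4 of 16 rose and 1 fell, 5 and 3 adjusted over the list alone) stood at 0.0405, and at adjusted p = 0.12 with an estimated correlation. They lost the call without vehicle replicate 4 (0.0523) or 2 (0.11), pioglitazone replicate 1 (0.191) or 2 (0.19), rosiglitazone replicate 1 (0.167) or 2 (0.0699), or troglitazone replicate 4 (0.142).

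Troglitazone changed 156 probe sets, 91 higher and 65 lower (78 and 55 genes), and 11 lists, 6 of them with an estimated correlation. With median centring 103 probe sets were higher and 48 lower, and with quantile normalisation 72 and 69. The count was 84, 91 and 86 without vehicle replicate 4, 1 and 2, and 72, 98 and 85 without troglitazone replicate 4, 1 and 2. It was 55 with no set term, 37 in set 1 alone, 19 with no intensity trend, 89 with no filter and 40 in a fit of only the 2 groups. Of 54 named genes that passed, 28 kept the call without any one array.

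**Figure D1:**
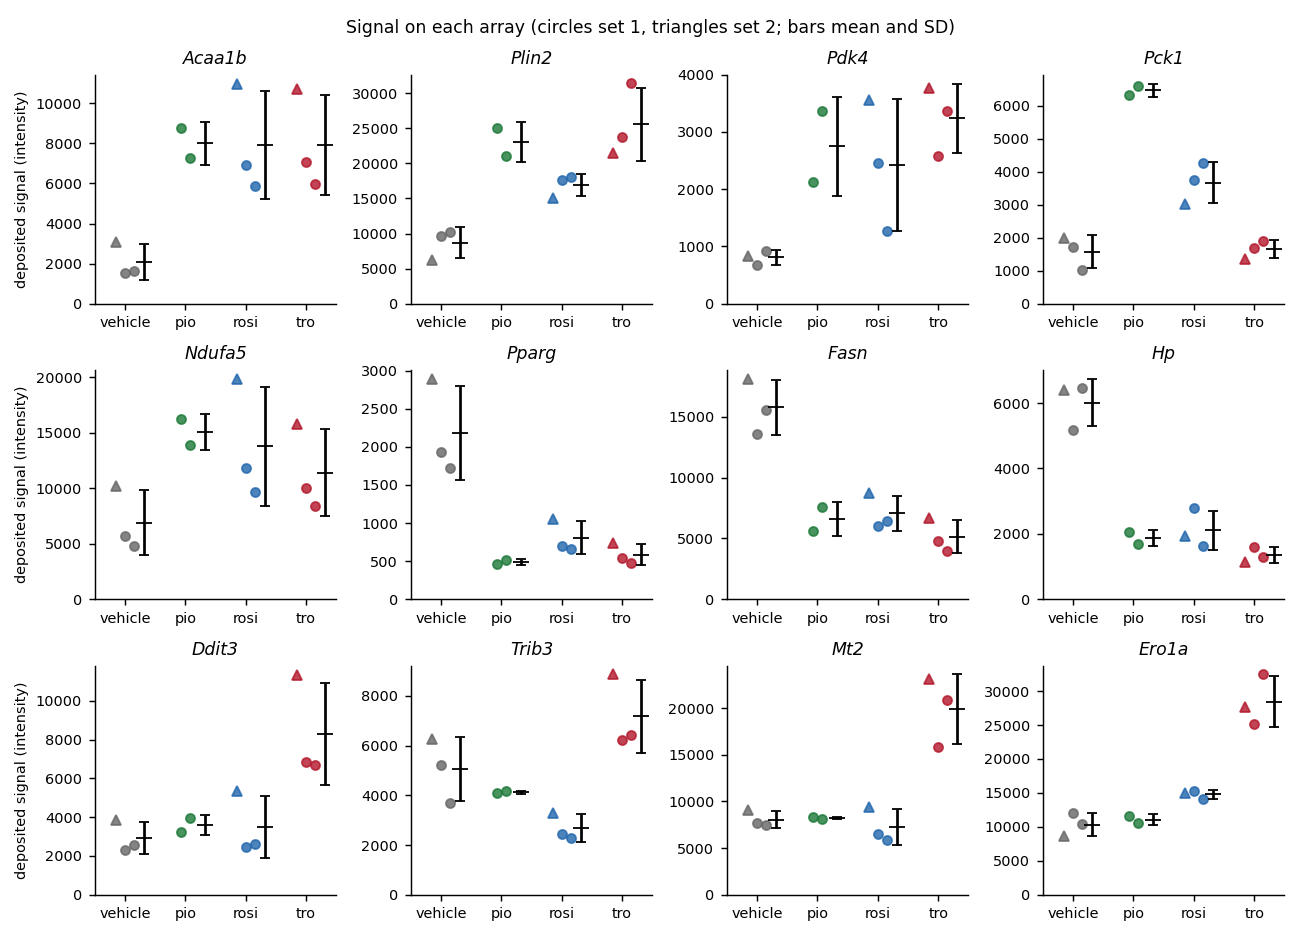
Deposited signal of 12 genes on each array, by group, on a linear axis from 0; circles are set 1, triangles set 2, and bars show mean and SD. Mean Pparg signal was 2182 with vehicle, 486.8 with pioglitazone, 805.5 with rosiglitazone and 584.5 with troglitazone; mean Ero1a signal was 10350, 11080, 14780 and 28450.

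Across the 3 drugs, 60 probe sets (50 genes) changed with each drug in the same direction, 38 higher and 22 lower, out of 240 that changed with any, and 0 changed in opposite directions. Acaa1b, Chchd10, Anxa2 and Angptl4 were higher with each drug, and Pparg, Thrsp, Gsn and Hp lower, and these 8 kept each call without any one array. Averaged over the drugs (n = 8 against 3), Plin2 rose 2.44-fold (1.29 ± 0.12, adjusted p = 1.8e-05), and Cidec 2.33-fold (1.22 ± 0.11, adjusted p = 1.23e-05). Angptl4 rose 2.25-fold (1.17 ± 0.12, adjusted p = 3.96e-05) and Ndufa5 2.12-fold (1.08 ± 0.11, adjusted p = 5.26e-05), with each of the 8 arrays above the vehicle mean of its set. Pparg was 3.36-fold lower (-1.75 ± 0.18, adjusted p = 3.99e-05), Hp 3.51-fold (-1.81 ± 0.17, adjusted p = 2.45e-05), Fasn 2.47-fold (-1.30 ± 0.12, adjusted p = 1.8e-05) and Retn 2.19-fold (-1.13 ± 0.16, adjusted p = 0.000772), with each of the 8 below it.

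Of the 12 lists called for the mean of the drugs, 8 held with an estimated correlation. They are oxidative phosphorylation (camera adjusted p = 1.47e-21, and 0.0122 with an estimated correlation), PPARγ targets and lipid droplets (6.06e-11, and 0.0176), fatty acid oxidation (1.77e-10, and 0.0176) and glycolysis (6.06e-11, and 0.0149), and further peroxisomal lipid metabolism (8.56e-05, and 0.0176), fatty acid and triglyceride synthesis (3.74e-05, and 0.0176), extracellular matrix (0.000123, and 0.0176) and cholesterol synthesis and uptake (0.000331, and 0.0219). The citric acid cycle (9.85e-08), lipolysis (0.00742), inflammatory genes (0.0396) and thermogenic genes (0.0478) lost the call: adjusted p = 0.0577, 0.183, 0.179 and 0.152 with an estimated correlation. The inflammatory list also lost it without vehicle replicate 4 (0.193), pioglitazone replicate 1 (0.0806), rosiglitazone replicate 1 (0.0662) or 4 (0.053), or troglitazone replicate 4 (0.0752). The thermogenic list lost it without vehicle replicate 2 (0.0576) or 4 (0.124), pioglitazone replicate 1 (0.0695), rosiglitazone replicate 1 (0.0783) or 4 (0.0534), or troglitazone replicate 2 (0.0574) or 4 (0.0852). Endoplasmic reticulum stress genes had 4 of 19 higher but were not called (adjusted p = 0.0651); their median was -0.16, their mean 0.04, and the test pointed up.

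The lists of adipokines, adipogenic transcription factors, insulin signalling, xenobiotic metabolism, heat shock and cell cycle, and the markers of macrophages, skeletal muscle, smooth muscle, osteoblasts and chondrocytes, endothelium and epithelium, were called by camera with none of the 3 drugs. Fry called adipogenic transcription factors with pioglitazone (adjusted p = 0.0321) and troglitazone (0.035), heat shock with rosiglitazone (0.032), epithelium with pioglitazone (0.00925) and smooth muscle with troglitazone (0.0429). For these lists the adjusted p by camera for the mean of the drugs was 0.202 for adipokines, 0.131 for adipogenic transcription factors, 0.571 for insulin signalling (median -0.01, test pointing up), 0.266 for xenobiotic metabolism, 0.245 for heat shock and 0.571 for cell cycle. For the markers of other cells it was 0.536 for macrophages, 0.63 for skeletal muscle, 0.649 for smooth muscle, 0.571 for osteoblasts and chondrocytes, 0.883 for endothelium and 0.571 for epithelium.

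Of the 25 tested genes that were fixed beforehand, Pdk4 rose with pioglitazone as well (1.90, adjusted p = 0.00715), but not without pioglitazone replicate 2 (0.101) or vehicle replicate 1 (0.0668). With rosiglitazone Pdk4 rose by 1.47 (adjusted p = 0.0125), but not without rosiglitazone replicate 1 (0.102) or 4 (0.131) or vehicle replicate 1 (0.0884) or 4 (0.129). Retn was at -0.84 with rosiglitazone (adjusted p = 0.0394) and at -0.89 with pioglitazone (adjusted p = 0.0782). The former lost its call without vehicle replicate 1 (0.179) or 2 (0.24), rosiglitazone replicate 1 (0.178), 2 (0.198) or 4 (0.0863), or troglitazone replicate 1 (0.0731), 2 (0.0662) or 4 (0.0774). Values that passed with none of the drugs, in the order pioglitazone, rosiglitazone and troglitazone, were 1.08, 0.26 and 0.14 for Cpt1a, the carnitine transferase of fatty acid oxidation, and 0.48, 0.16 and 0.03 for the lipase Lipe. They were 0.58, 0.66 and 0.05 for Ucp1, the uncoupling protein of brown fat, and -0.42, -0.14 and -0.11 for leptin (Lep). Oxidative stress genes gave -0.89, 0.25 and -0.22 (Nqo1), 1.26, 0.42 and 1.01 (Hmox1), and -0.42, -0.32 and -0.12 (Cat). For the mean of the drugs Hmox1 did pass, but only 4 of the 24 alternatives kept that call (log2 0.605 to 1.134). Tnf gave -0.17, -0.39 and 0.89, and Saa3, an acute phase protein, -0.08, 0.05 and -0.05.

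For the mean of the 3 drugs 251 probe sets passed, 150 higher and 101 lower (130 and 86 genes). The count was 127, 122 and 115 without vehicle replicate 4, 1 and 2, 163 without rosiglitazone replicate 4, 159 without troglitazone replicate 4, 84 with no set term, 56 in set 1 alone and 30 with no intensity trend. Of these probe sets 59.8% were higher, 50.7% with quantile normalisation and 69.9% with median centring; with no set term 37 were higher and 47 lower, and with no intensity trend 11 and 19. Across all probe sets, which are not independent replicates, log2 fold changes correlated at 0.475 between pioglitazone and rosiglitazone, 0.522 between pioglitazone and troglitazone and 0.561 between rosiglitazone and troglitazone. The same vehicle arrays serve all 3, and data simulated with no drug effect gave 0.433, 0.432 and 0.5. The covariances exceeded the simulated ones by 0.041, 0.045 and 0.041. Probe sets called in the same direction numbered 50 higher and 25 lower for pioglitazone and rosiglitazone (0.58 and 0.183 by chance), 42 and 24 for pioglitazone and troglitazone (0.574 and 0.177), and 56 and 44 for rosiglitazone and troglitazone (0.713 and 0.371). The simulated data shared 0, which decides nothing about this overlap, because with no drug effect there is little to call. The values by chance take the comparisons as independent, although they share the vehicle arrays. With 3 vehicle arrays the controls cannot be split, so part of the excess of shared calls may come from sharing them.

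**Figure D2:**
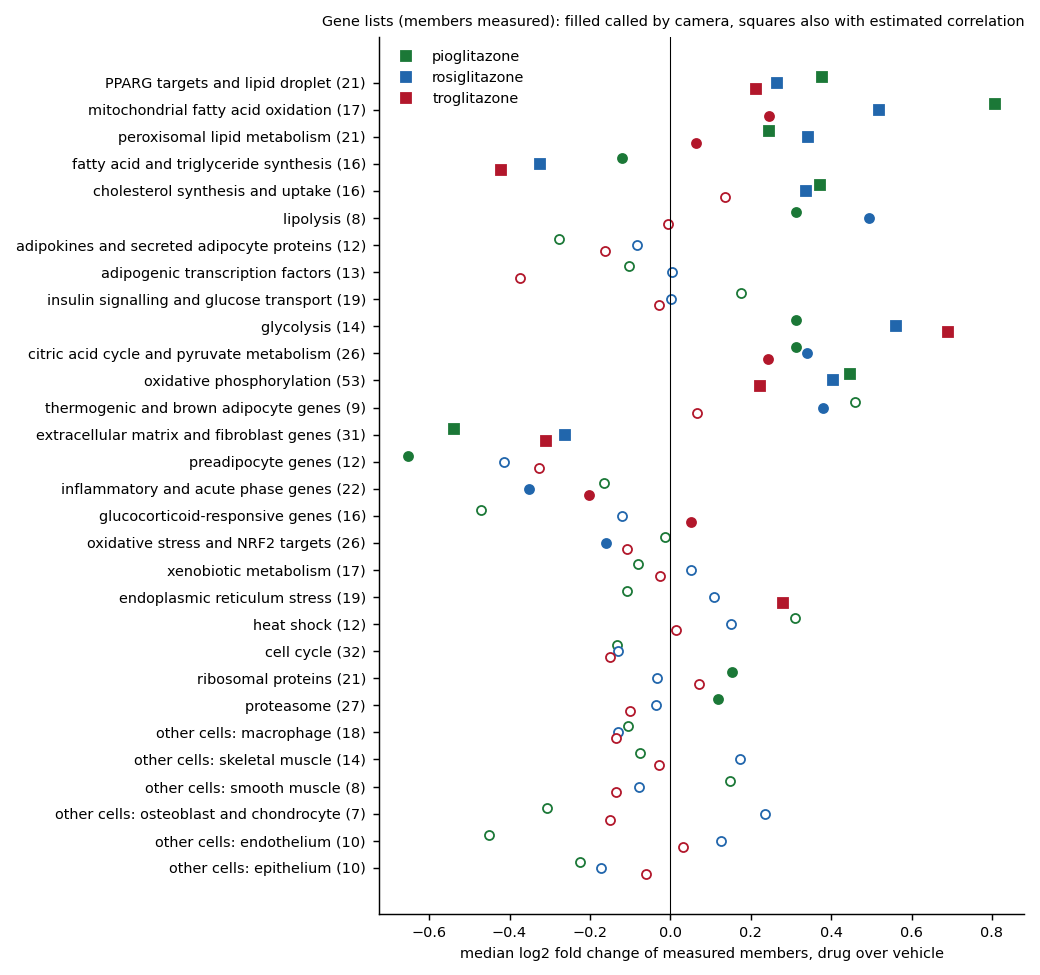
Median log2 fold change of the measured members of each of the 30 lists for each drug against vehicle; filled symbols were called by camera, squares also with an estimated correlation, open symbols not. Medians for oxidative phosphorylation were 0.45, 0.40 and 0.22 with pioglitazone, rosiglitazone and troglitazone, and for glycolysis 0.31, 0.56 and 0.69.

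Troglitazone and pioglitazone are the pair measured at the same dose, 20 µM. Ero1a was 2.64-fold higher with troglitazone than with pioglitazone (log2 difference 1.40 ± 0.16, 95% interval 1.06 to 1.74, n = 3 against 2, limma adjusted p = 0.00148), with signals of 28450 ± 3754 and 11080 ± 806.7. The other probe set of Ero1a differed likewise (log2 2.31, adjusted p = 0.00059). Mt2 was 2.17-fold higher (1.12 ± 0.15, interval 0.79 to 1.44, adjusted p = 0.00851), with signals of 19910 ± 3739 and 8257 ± 120.5. Pck1 was 3.88-fold lower (-1.96 ± 0.26, interval -2.52 to -1.39, adjusted p = 0.00851), with signals of 1655 ± 281.1 and 6467 ± 192.1. These 4 probe sets, 3 higher and 1 lower, are all that passed. For other genes the intervals bound the difference without excluding it: Pparg -0.48 to 0.56, Angptl4 -0.46 to 0.23, Pdk4 -0.57 to 0.76. The intervals of Fasn (-0.88 to -0.18) and Retn (-1.25 to -0.33) lay under 0, but the adjusted p was 0.53 and 0.36.

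Ero1a lost the call without pioglitazone replicate 1 (adjusted p = 0.0542). Mt2 lost it without pioglitazone replicate 1 (0.236) or 2 (0.0694), rosiglitazone replicate 1 (0.0612), or troglitazone replicate 2 (0.118) or 4 (0.0521). Pck1 lost it without pioglitazone replicate 1 (0.236) or 2 (0.0872), rosiglitazone replicate 1 (0.0612), or troglitazone replicate 1 (0.101) or 4 (0.0521). The count was 1 without pioglitazone replicate 1, 7 without pioglitazone replicate 2, 2 without rosiglitazone replicate 1 and 2 without troglitazone replicate 4. With limma it was 1 with no set term, 0 in set 1 alone (629 at an unadjusted p under 0.05), 0 with no intensity trend (657), and 0 in a fit of only the 2 groups (812). It was 4 others, 0 higher and 4 lower, with no filter, and 25 others, 3 higher and 22 lower, without the 2 arrays that stand apart.

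Camera called 12 lists between troglitazone and pioglitazone, 4 higher and 8 lower with troglitazone, and 0 with an estimated correlation (5 with fry). Endoplasmic reticulum stress genes were higher (median 0.52, 1 of 19 passed, 4 adjusted over the list alone; adjusted p = 3.84e-06, and 0.0544 with an estimated correlation), as were glycolysis genes (0.38, 0 of 14 passed, 4 adjusted over the list alone; 3.84e-06, and 0.0544). Oxidative phosphorylation genes were lower (-0.27, 0 of 53 passed, 4 adjusted over the list alone; 1.36e-10, and 0.0544), as were those of peroxisomal lipid metabolism (-0.33; 0.000945, and 0.0544). With no set term both calls were lost (adjusted p = 0.145 and 0.211), and the oxidative phosphorylation median was -0.12. The other 8 called lists each lost the call without at least 1 array: 7 without pioglitazone replicate 2 (adjusted p from 0.0522 to 0.457), where the count was 5, and lipolysis without pioglitazone replicate 1 (0.0953).

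Troglitazone and rosiglitazone were given at different doses, 20 µM and 1 µM. Mt2 was 2.76-fold higher with troglitazone (1.47 ± 0.13, n = 3 against 3, adjusted p = 0.000172), Trib3, a pseudokinase induced by CHOP, 2.67-fold (1.42 ± 0.14, adjusted p = 0.000292) and Ddit3 2.46-fold (1.30 ± 0.14, adjusted p = 0.000625). Signals of Trib3 were 5058 ± 1289 with vehicle, 2683 ± 546.5 with rosiglitazone and 7170 ± 1484 with troglitazone, and against vehicle the fall with rosiglitazone passed (-0.90 ± 0.14, adjusted p = 0.0034). Mt1 (1.94-fold, 0.96 ± 0.14, adjusted p = 0.0116), Ero1a (1.92-fold, 0.94 ± 0.14, adjusted p = 0.0132) and Npc1, the lysosomal cholesterol transporter (2.16-fold, 1.11 ± 0.18, adjusted p = 0.038), were higher too. With a further probe set of Ero1a these are the 7 that passed, 7 higher and 0 lower. Of 19 endoplasmic reticulum stress genes 3 were higher (6 adjusted over the list alone; median 0.42, camera adjusted p = 9.37e-05, but adjusted p = 0.103 with an estimated correlation). Oxidative phosphorylation genes were lower (median -0.20, adjusted p = 2.09e-06, and 0.103 with an estimated correlation), as were those of lipolysis (-0.25, 0.00403, and 0.217).

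Of the 7 probe sets between troglitazone and rosiglitazone, those of Mt2, Trib3 and Ddit3 kept the call without any one array. Ero1a lost it without rosiglitazone replicate 1 (adjusted p = 0.227), 2 (0.24) or 4 (0.099), or troglitazone replicate 2 (0.147) or 4 (0.34). Mt1 lost it without rosiglitazone replicate 1 (0.227), 2 (0.192) or 4 (0.132), or troglitazone replicate 1 (0.13) or 2 (0.143). Npc1 lost it in 10 of the 11 fits that left out 1 array, those without vehicle replicate 4 (0.0593) or 2 (0.0907), pioglitazone replicate 1 (0.0815) or 2 (0.0855), rosiglitazone replicate 1 (0.328), 2 (0.177) or 4 (0.167), or troglitazone replicate 1 (0.296), 2 (0.143) or 4 (0.562). The count was 3 without rosiglitazone replicate 4, 1 or 2 or troglitazone replicate 2, and 4 without troglitazone replicate 4. With limma it was 0 with no set term (535 at an unadjusted p under 0.05), 0 in set 1 alone (848), 0 with no intensity trend (744), 0 in a fit of only the 2 groups (706) and 0 without the 2 arrays that stand apart (765). Camera called 9 lists in all, 5 higher and 4 lower, 0 with an estimated correlation and 6 with fry, and 5 without rosiglitazone replicate 4.

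Between rosiglitazone (1 µM) and pioglitazone (20 µM) limma called 0 probe sets, with 812 at an unadjusted p under 0.05. The smallest p-values belonged to Myh8 (log2 2.01), Cebpd (1.88), Scgb1b2 (2.35), Tyms-ps (0.85) and Fgfr4 (1.88) on the higher side, all at an adjusted p of 0.589. On the lower side they belonged to Rxrb (-1.76), Trib3 (-0.81), Anapc5 (-0.79), Mtx1 (-1.78, adjusted p = 0.524) and Ddb1 (-0.61); none passed. Camera called 6 lists, 1 higher and 5 lower, and 0 with an estimated correlation (0 with fry). Ribosomal protein genes were lower with rosiglitazone (median -0.29, adjusted p = 2.19e-06, and 0.221 with an estimated correlation). The other 5 each lost the call without pioglitazone replicate 2 (adjusted p from 0.0956 to 0.875). The list count was 2 without pioglitazone replicate 1, 1 without pioglitazone replicate 2, and 2 without rosiglitazone replicate 4, 1 or 2. No filter on dim probe sets gave 3 probe sets, and median centring moved the median of all genes from 0.06 to -0.10.

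The effects of rosiglitazone and troglitazone were also compared between the sets. With limma, 0 probe sets passed for a difference of the rosiglitazone effect between set 1 and set 2 and 0 for that of troglitazone, with 437 and 288 at an unadjusted p under 0.05; with no filter 21 passed for rosiglitazone. Each of the 159 and 156 probe sets called for these drugs had the same sign in set 2. Over them the log2 fold changes of the sets correlated at 0.922 and 0.948 across probe sets, against 0.0976 and 0.132 over all probe sets. The called probe sets were chosen on both sets together, so that agreement of sign is not an independent test.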

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

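The exact permutation test and the tests below were chosen only after the results were seen, except the test without pioglitazone replicate 2 and the other splits of the arrays. The Gapdh control probe set for the 3' end of the transcript was set aside from the tests above with the other controls. It was 1.48-fold higher in the drug arrays (69470 ± 7910, SD, n = 8) than in the vehicle arrays (46760 ± 1502, n = 3). Each of the 8 drug arrays, from 55084.3 up, lay above the highest vehicle array at 48340.4. The probe set was singled out for this separation, so a permutation p at the smallest possible value followed from the choice. The exact permutation p was 0.00606, the smallest that 165 splits allow, and 0.0968 adjusted over 16 control probe sets. These splits ignore the set; within the sets the exact permutation p was 0.0119, the smallest that 84 splits allow, and 0.19 adjusted. The probe sets for the middle and the 5' end of Gapdh were 1.58-fold and 1.5-fold higher, with exact permutation p-values of 0.0121 and 0.0788.

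Oxidative phosphorylation transcripts were higher with each drug, with a lower median with troglitazone whose difference was not called with an estimated correlation (adjusted p = 0.0544 against pioglitazone, 0.103 against rosiglitazone) and was -0.12 against pioglitazone with no set term (adjusted p = 0.145). If RNA integrity accounted for the rise, adding the beta-actin 3' to 5' ratio to the model would remove it. The median over the list was 0.316 with the ratio (0.293 to 0.4 with any one array left out) and 0.336 without. This cannot decide the question, because within each set the ratio differed little between vehicle and drug arrays, except on pioglitazone replicate 2 (4.86). In set 1 the ratio was 2.23 and 2.27 with vehicle and 1.79 to 2.09 on the other drug arrays. If scaling of bright probe sets accounted for the rise, ribosomal protein (0.0573) or proteasome genes (-0.0314) would move as far. The list median exceeded the larger by 0.278 (0.176 to 0.305), which speaks against scaling as the whole origin for the mean of the drugs. With pioglitazone, camera at the preset correlation called the ribosomal and proteasome lists higher too, but not with an estimated correlation. It also called both between troglitazone and pioglitazone. The test was not run for single drugs or for that pair. With quantile normalisation, the oxidative phosphorylation median was 0.207 for the mean of the drugs, 0.277 with pioglitazone and 0.106 with troglitazone. The difference between troglitazone and pioglitazone was -0.255 without pioglitazone replicate 2, against -0.267 with all arrays and -0.3 without pioglitazone replicate 1. That part stays open, because the interval set beforehand (-0.328 to -0.131) resampled genes and not arrays, and 1 pioglitazone array remained.

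The 7 probe sets called between troglitazone and rosiglitazone, of Ddit3, Trib3, Ero1a, Mt1, Mt2 and Npc1, had a median difference of 1.23; the endoplasmic reticulum stress list had one of 0.42, with adjusted p = 0.103 with an estimated correlation. Without rosiglitazone replicate 2, which stood apart, the median was 1.28 (1.06 to 1.36 with a further array left out), and 3 of the 7 (Mt2, Trib3 and Ddit3) still passed, while Ero1a, Mt1 and Npc1 lost the call at values of 0.87, 0.95 and 1.19, near those with it (0.94, 0.96 and 1.11), and 0 passed without the 2 arrays that stand apart. Over all 24 alternatives, that fit included, the difference lay at 1.35 to 1.57 for Mt2, 1.37 to 1.52 for Trib3 and 1.23 to 1.42 for Ddit3. It lay at 0.99 to 1.21 for Npc1, 0.85 to 1.05 for Ero1a and 0.84 to 1.06 for Mt1. The molar dose alone would leave these probe sets alike with pioglitazone and troglitazone, both at 20 µM, and the median difference was 0.949 (0.901 to 1.04). Neither median decides anything, because the probe sets were chosen for being high on the same troglitazone arrays. Singly, Ero1a (1.40 and 2.31) and Mt2 (1.12) passed between these 2 drugs. Of the 24 alternatives, 17 kept the call of Ero1a (1.30 to 1.53 for the probe set at 1.40) and 11 that of Mt2 (0.98 to 1.25). This goes against molar dose alone for these 2 genes only as far as the calls hold. Ddit3 (0.90), Trib3 (0.61), Mt1 (0.59) and Npc1 (0.95) did not pass. Rosiglitazone at 20 µM was not measured, so for the other 4 the dose stays open.

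Pparg and 4 fatty acid synthesis transcripts, taken because they fell, had a median of -1.3 for the mean of the drugs, while the fixed list of 16 synthesis genes had one of -0.22, with 1 member that rose, and lost its call with pioglitazone (adjusted p = 0.0757 with an estimated correlation). A lower share of adipocytes in the treated cultures would lower other adipocyte markers as well, but the median over 8 markers was 0.0556 (-0.034 to 0.103 with any one array left out): Adipoq -0.21, Fabp4 0.40, Lpl -0.31, Cebpa -0.11, Slc2a4 -0.01, Lipe 0.23, Cd36 0.12 and Cidec 1.22. None of these 8 fell as far as the pattern, as a loss of adipocytes alone would require. Several of them are PPARγ targets, however, whose rise in the remaining adipocytes could hide a loss. The adipokine Retn, not among the 8, did fall (-1.303 to -0.989 over the alternatives). The extracellular matrix list was lower too (median -0.36, camera adjusted p = 0.000123). Whether the drugs act on those genes was not tested. The markers therefore speak only against a loss that no such rise hides, and the matrix list decides nothing. Scaling would lower other probe sets of the same brightness, but the median over 1749 of them was 0.0274 (0.0204 to 0.0398). The arrays had already been scaled to the same trimmed mean, which left little room for such a shift. The value therefore shows only that probe sets of this brightness did not fall together.

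Other splits of the arrays, which ignored the set, gave fewer calls. For the mean of the drugs the labels of the 4 groups were given to the arrays at random. The real grouping gave 251 probe sets against at most 1 under these labels, and 12 lists against at most 11. Each real count was the highest of 100 labelings, the real one included. Under other labels, vehicle and drug arrays share a group, which widens the spread within groups and can itself lower the counts. With 11 lists called under other labels, the list count by camera at the preset correlation sets the real grouping apart by little. For rosiglitazone against vehicle the values were 159 against 0 probe sets and 13 against 6 lists, for troglitazone against vehicle 156 against 0 and 11 against 4, and for troglitazone against rosiglitazone 7 against 0 and 9 against 3; with 10 splits each these are too few for a share under 0.05.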

How the results depend on the processing

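None of the 217 called values among the 371 gene values reversed under the alternatives that gave them a value, but many lost the call. Quantile normalisation gave 364 of the 371 and the higher floor 357. Values near 0 that did not pass can change sign, as median centring moves the median of all genes. Acaa1b, Chchd10 and Anxa2 with rosiglitazone and troglitazone and Pparg, Fasn, Gsn, Hp, Plin2 and Ddit3 with troglitazone passed under all 24 alternatives. Counts of probe sets for pioglitazone, rosiglitazone, troglitazone and their mean were 25, 40, 55 and 84 with no set term, 23, 19, 37 and 56 in set 1 alone, and 6, 6, 19 and 30 with no intensity trend. A fit of only the groups compared gave 0, 18 and 40 for the drugs, no filter 99 for rosiglitazone and 89 for troglitazone, and leaving out the 2 arrays that stand apart, an alternative chosen after seeing the data, 58 for rosiglitazone. Set 1 alone, single groups and left-out arrays have fewer samples; for the intensity trend, the set term and the filter the cause was not tested. Replicate numbers as blocks gave 114, 162, 144, 247, 4, 0 and 5 over the 7 contrasts.

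Between troglitazone and pioglitazone (4) the count was 1 with no set term, 0 in set 1 alone, 0 with no trend, 0 with only the groups compared, 25 without the 2 arrays and 4 with no filter, with 0 of the original 4 among the last 2 of these. Between troglitazone and rosiglitazone (7) it was 0 in each of these 5 alternatives and 4 with no filter. Between rosiglitazone and pioglitazone it was 3 with no filter and 0 otherwise. The difference of the rosiglitazone effect between sets was 0, and 21 with no filter. Leaving out 1 array gave 43 to 111 for pioglitazone (59 of the 111 among the original 106), 74 to 158 for rosiglitazone, 72 to 162 for troglitazone, 115 to 236 for the mean, 1 to 7, 0 to 0 and 3 to 6 for troglitazone against pioglitazone, rosiglitazone against pioglitazone and troglitazone against rosiglitazone.

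With an estimated correlation 6, 8 and 6 lists were called for the 3 drugs and 0 for each pair. Lists between rosiglitazone and pioglitazone (6) were 0 with fry, 2 with quantile normalisation, 0 with no set term, 2 in set 1 alone, 1 with the actin covariate, also chosen after seeing the data, and 0 without the 2 arrays. Between troglitazone and pioglitazone (12) they were 5 with fry, 4 with no set term, 5 with the actin covariate and 5 without the 2 arrays, and between troglitazone and rosiglitazone (9) 4 in set 1 alone. With 1 array left out, lists numbered 10 to 13, 9 to 13 and 8 to 12 for the drugs, 10 to 13 for the mean, and 5 to 13, 1 to 7 and 5 to 9 for the pairs in the order above. The proteasome list reversed in 3 cases: pioglitazone against vehicle without the 2 arrays (adjusted p = 0.918), and rosiglitazone against pioglitazone without the 2 arrays (0.469) or without pioglitazone replicate 2 (0.875; 8.51e-06 to 0.875 with 1 array left out).

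Correlations of drug effects across genes were, for pioglitazone and rosiglitazone, 0.577 with the higher floor, 0.53 with no set term, 0.521 in set 1 alone, 0.379 with the actin covariate and 0.361 without the 2 arrays (0.361 to 0.558 with 1 array left out). For pioglitazone and troglitazone they were 0.497 with the lower floor, 0.604 with the higher, 0.566 in set 1 alone, 0.348 with the covariate and 0.411 without the 2 arrays (0.413 to 0.607), and for rosiglitazone and troglitazone 0.639 with the higher floor and 0.511 in set 1 alone (0.439 to 0.694). The cause was not tested. Signal over background limits what can be seen in dim transcripts, since 20.99% of the tested values lay at the floor.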

Other observations

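The grouping of genes in this part was chosen only after the values were seen. Averaged over the 3 drugs (n = 8 against 3), Gstm1, a glutathione transferase, was 1.72-fold lower (-0.78 ± 0.11, limma adjusted p = 0.0011), with signals of 17750 ± 2090 with vehicle (SD), 11450 ± 2732 with pioglitazone, 8897 ± 798.7 with rosiglitazone and 10410 ± 999 with troglitazone. A dimmer probe set of Gstm1 pointed the other way for this mean without passing (0.284, limma adjusted p = 0.885). Cyp2f2, a cytochrome P450, was 2.23-fold lower (-1.16 ± 0.19, adjusted p = 0.00296), a call lost without vehicle replicate 4 (0.0548). Cyp1b1, a cytochrome P450 of hydrocarbon and oestrogen metabolism, was 4.59-fold lower (-2.20 ± 0.40, adjusted p = 0.0061), a call lost without vehicle replicate 1 (0.0926) or 2 (0.0928). The lists of xenobiotic metabolism (adjusted p = 0.266) and NRF2 targets (0.63) were not called for the mean of the drugs, and the former had 8 members above 0 and 9 under it. Other enzymes of this kind rose with each drug: Cbr3 (1.62, 1.16 and 1.41 with pioglitazone, rosiglitazone and troglitazone) and the epoxide hydrolase Ephx2 (1.28, 1.03 and 1.38).

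The glucose transporter Slc2a1 rose for the mean of the drugs as well (1.49 ± 0.27, adjusted p = 0.00592), with signals of 411.8 ± 161.3 with vehicle, 974.5 ± 425.4 with pioglitazone, 965.3 ± 128.4 with rosiglitazone and 1558 ± 252.5 with troglitazone; without vehicle replicate 4 the adjusted p was 0.0754. The insulin-responsive transporter Slc2a4 did not pass for the mean of the drugs (-0.0057), nor with pioglitazone (0.16), rosiglitazone (0.0495) or troglitazone (-0.2269).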
